A study of Nicotiana tabacum with 6 samples.

How the data were processed

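Leaf RNA of tobacco (Nicotiana tabacum, cultivar Petit Havanna as the labels spell it) was measured on 6 Affymetrix tomato GeneChip arrays, 2 for wild type, 2 for plants with a deletion of the plastid gene psaA and 2 for plants with a deletion of the plastid gene psbA. Per the labels' protocols, plants were kept in culture bottles under dim light with 16 h of light and 8 h of dark, in selection medium with 500 mg/L spectinomycin. Leaves were taken 2 to 3 weeks after subculture, and biotin-labelled cRNA was made from 5 ug of total RNA. The growth text is the same for all 6 samples, wild type included, but whether the wild-type plants were in fact kept on spectinomycin is unclear. If they were not, the drug and the genotype cannot be separated in any comparison with wild type or in the changes shared by the mutants. If they were, a drug response that differs between wild type and mutants cannot be separated from the deletions either. The labels call the 2 arrays of a group biological replicates, and do not say whether they came from separate plants or separate lines.

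The deposited table holds log2 values for 10209 probe sets on each array. Per the submitters' processing notes, RMA and GCRMA were used, 2 methods that correct background, normalize between arrays and summarise the probes of a probe set. The notes give neither version, nor which method made the deposited values, and the base of the logarithm is not stated. Base 2 was taken because both methods give it, so each fold change rests on that reading. Each of the 10209 probe sets had a median of 0 over the 6 arrays, within 1e-06, so the deposited values had been centred per probe set and keep differences between arrays but no signal level. Whether a probe set was bright or dim, and so how near background it lay, cannot be read from them. Values ran from -6.13 to 3.05.

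Because tobacco RNA was hybridised to probes designed on tomato sequences, a probe set reports a tobacco transcript only as far as the sequences match, and mismatches can lower or hide a signal. The 3 genotypes share one tobacco background, so this acts on all arrays alike. Gene names came from the platform's annotation of 2007: 909 probe sets had 1 gene symbol (207 of them a LOC number), 0 had several and 9192 had none. They stand for 803 tomato genes, 627 of which have a symbol other than a LOC number. No titles were given, 0 of the tomato gene IDs occur in the tobacco gene table, and genome positions are not used here. No probe set was tied by symbol to psaA, psbA or another plastid-encoded gene. Clauses on what a gene does are background on the tomato gene of that symbol.

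The 108 Affymetrix control probe sets were left out, which left 10101 tested probe sets. A linear model was fitted to all 6 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 3 residual degrees of freedom and 5.39 prior degrees of freedom. From it came 3 contrasts: psaA deletion minus wild type, psbA deletion minus wild type and psbA deletion minus psaA deletion, the last being the test of the difference between the mutants' effects. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the 10101 probe sets, and an adjusted p under 0.05 is called a change. Errors are limma's standard errors (SE) of the log2 difference, with n = 2 arrays per group. They measure only the spread between these arrays. Precision is limited by the number of arrays: the median SE was 0.125. Simulated data for the psaA comparison had 200 of 10101 probe sets changed in each of 20 draws. In these the fit recovered 17.2% of log2 changes of 0.5, 91.4% of changes of 1 and 99.2% of changes of 1.5. False calls made up 4.51% of all simulated calls, and 0 calls had the wrong sign. The draws had independent normal errors with variances from the fitted model. A false share near the threshold of 0.05 was therefore built in and does not measure false calls on the real arrays. The comparison itself called 1083 probe sets. With fewer changed probe sets the Benjamini-Hochberg adjustment is stricter, so the simulated shares may understate recovery in the data, above all at 0.5. The plots were drawn with matplotlib 3.10.9.

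Design, tests, lists and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among called probe sets whose arrays do not overlap between groups. It also takes the 3 genes with the smallest p of each list in each mutant against wild type, and the control probe sets of housekeeping genes at their 3', middle and 5' parts, which are given as the median per gene and as 3' minus 5' differences. Of the list genes that did not pass, only a part is printed. The rule chose 1 probe set per gene by its mean signal. Centring removed that signal, so a plain probe set was taken before one with a suffix for several transcripts, then by ID order. List members CAB5, PSBO, PSBR, ZEP, HMGR, CHI9, PDS, DXR, CCD1A, AOX1a and opr2, the genes named below from lists added later, the genes ADC and FPPS1, and the reporter and unnamed probe sets were chosen after their values were seen.

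A total of 23 gene lists were matched by symbol, and 10 ambiguous symbols were excluded before any fit. Lists covered plastid-encoded genes, photosystem I, photosystem II with its light-harvesting complex, photosynthetic electron transport, the Calvin cycle, tetrapyrroles, carotenoids and isoprenoids, antioxidant enzymes, heat shock proteins, pathogenesis-related and wound genes, and ethylene and abscisic acid. They also covered phenylpropanoids, sugars and starch, nitrogen, cytosolic translation, plastid gene expression, proteolysis, respiration, the cell cycle, and markers of meristem, epidermis, xylem and root. Of these, 13 had at least 3 measured genes and were tested with camera at its preset correlation of 0.01 against the 627 genes with a symbol. Another 8 had 1 or 2 genes and are given as values, and 2 (plastid-encoded genes and the Calvin cycle) matched 0 genes. Camera with an estimated correlation and fry were run beside it. Another 5 lists and 1 pooled photosynthesis list were added after seeing the data.

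Alternatives were array medians set to 0, only the 4 arrays compared, the replicate number as a block, trend and robust eBayes, array weights, a 2-fold minimum, treat against 1.2-fold, 1 probe set per gene, leaving out probe sets that can measure several transcripts, and leaving out each array. Scaling on poly-A controls (36 probe sets for bacterial RNAs that the Affymetrix protocol adds to the RNA before labelling) and on hybridisation controls (27 probe sets for labelled RNAs added at hybridisation) was chosen after seeing the data. So was the background of all tested probe sets. A second quantile normalization and both filters on dim probe sets need signal levels and were not run. The correlation between the mutants was set beside 100 simulated draws of unchanged groups that share the wild-type arrays. These draws gave 0 shared calls, and since unchanged groups give few calls at this threshold, they were not used to judge the count of shared calls.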

Results

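The study compared leaf transcripts of tobacco plants lacking psaA, the plastid gene for a reaction-centre protein of photosystem I, or psbA, the plastid gene for the D1 protein of photosystem II, with those of wild type, on 2 arrays per group. Replicate arrays differed with a standard deviation over probe sets of 0.208 (wild type), 0.206 (psaA deletion) and 0.229 (psbA deletion) on the log2 scale, against 0.308 to 0.371 for arrays of different groups. Whether wild type, like the mutants, was grown on spectinomycin is unclear from the labels, and if it was not, the drug and the genotype cannot be separated in comparisons with wild type. If it was, a drug response that differs between wild type and mutants cannot be separated from the deletions either. No probe set was tied to psaA or psbA, so the deletions themselves could not be checked on the arrays. Changes are log2 differences relative to the typical probe set of an array, since the deposited values were normalized between arrays. If the arrays were instead scaled on the added poly-A control RNAs, a choice made after seeing the data, the median of all probe sets moved to -0.23 in the psaA mutant, to -0.47 in the psbA mutant and to -0.22 for psbA minus psaA.

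What loss of psaA does to nuclear transcripts was the question of the psaA comparison. Genes of photosynthesis and carotenoid synthesis and a catalase gene were lower in the psaA mutant than in wild type, and several defence genes were higher. The largest fall among named genes was that of ca2 (gene ID 543803), 7.12-fold lower (log2 change -2.83, SE 0.113, n = 2 per group). CAT2 (543585), a catalase, was 4.42-fold lower (-2.14, SE 0.102), and VDE (543696), the violaxanthin de-epoxidase of the xanthophyll cycle, was 3.2-fold lower (-1.68, SE 0.103). GluB (543987), a beta-1,3-glucanase gene, rose most among named genes, 2.34-fold (1.23, SE 0.112). In each of these genes, as the rule for named genes requires, both psaA arrays lay on the same side of both wild-type arrays. The ca2 result held at a second probe set (-3.11), while the other pair gave -0.26 and -0.87 with adjusted p of 0.21 and 0.0508. A second VDE probe set gave -0.42 with adjusted p = 0.124.

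Of 6 nuclear genes for photosystem II and its light-harvesting complex, 5 fell and 1 did not pass, with a median of -0.97; adjusted over the list alone, 6 fell. The fall was 2.31-fold for the antenna gene CAB4 (-1.21, SE 0.125), 1.99-fold for PSBP (SE 0.107 on the log2 scale) and 1.98-fold for PsbQ (-0.98, SE 0.114), both parts of the oxygen-evolving complex. CAB5 (-0.96) and PSBO (-0.68) fell as well, and PSBR gave -0.33 with adjusted p = 0.0792. The list was lower than other genes by camera (adjusted p = 4.98e-06), but not with its correlation estimated from the arrays (adjusted p = 0.101 with an estimated correlation). Among lists too small to test, the photosystem I antenna gene CAB6A fell by 0.69 and the plastocyanin gene PETE fell by 0.82, while POR2, a protochlorophyllide reductase, gave -0.32 with adjusted p = 0.147 (unadjusted, it passed).

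Of 14 carotenoid, isoprenoid and tocopherol genes, 10 fell, 1 rose and 3 did not pass, with the same counts of 10 and 1 when adjusted over the list alone. Besides VDE, the fall was 1.13 for ZDS, the zeta-carotene desaturase, 1.01 for the carotene hydroxylase gene CrtR-b1, 0.87 for the phytoene synthase gene PSY2, 0.85 for the carotenoid cleavage gene CCD1B and 0.80 for ZEP, all as log2 differences lower than wild type. HDS and DXR of the plastid isoprenoid pathway fell by 0.78 and 0.76, PDS, the phytoene desaturase, fell by 0.68, and CCD1A fell by 0.42. The gene that rose was HMGR (0.78, SE 0.134), of the cytosolic mevalonate pathway. Camera put the list lower than other genes (adjusted p = 6.98e-06; adjusted p = 0.101 with an estimated correlation).

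**Figure D1:**
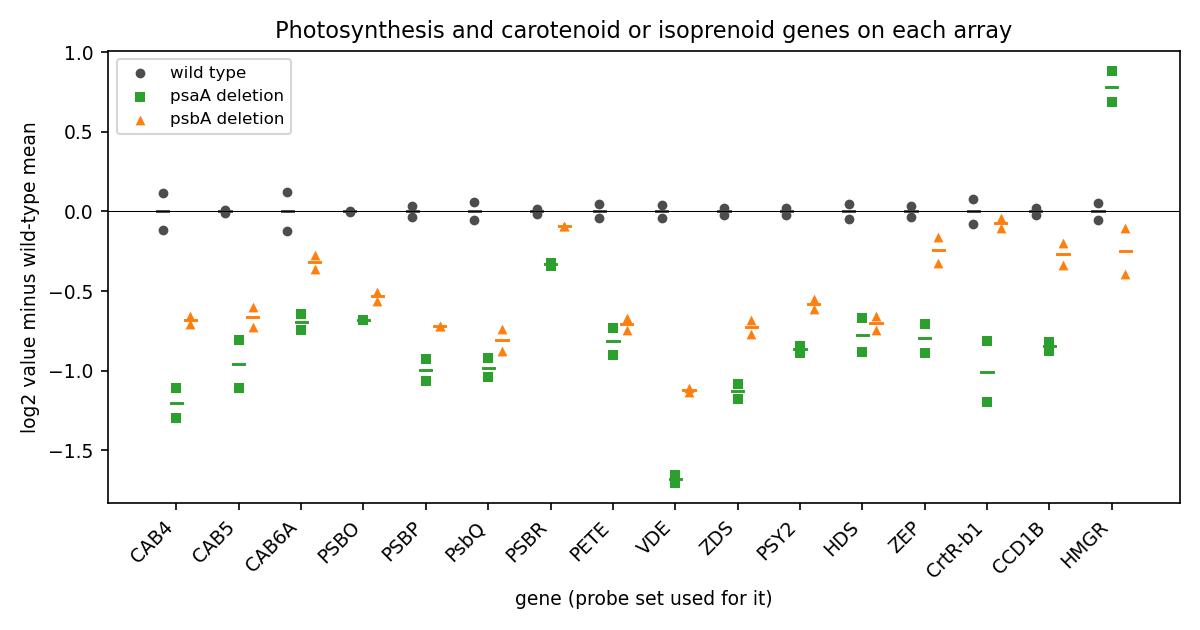
Log2 values of each array minus the wild-type mean for 16 photosynthesis and carotenoid or isoprenoid genes, with 2 points and a line at their mean for each group. In the psaA mutant the means ran down to -1.68 at VDE, CrtR-b1 was -1.01 in the psaA mutant and -0.07 in the psbA mutant, and HMGR lay above wild type in the psaA mutant (0.78).

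Of 24 pathogenesis-related and wound or jasmonate genes, 6 rose, 1 fell and 17 did not pass; adjusted over the list alone, 7 rose and 1 fell. GluB, PR-5 (0.86, SE 0.116), the chitinase genes CHI9 (0.87) and CHI14 (0.76), the lipoxygenase gene loxD (0.72) and the allene oxide cyclase gene AOC (0.69) rose, and another lipoxygenase gene, loxC, fell by 1.09. As a list they were not called (camera adjusted p = 0.327). NP24-I, an osmotin-like protein gene outside the list, rose by 0.91 (SE 0.101). Of 13 antioxidant genes, CAT2 and DHAR2 (-0.77) fell, APX2 (0.59) and AOX1a (0.47) rose and 9 did not pass, against 4 that rose and 2 that fell when adjusted over the list alone. Of 13 cell cycle genes, 3 fell on both counts, namely the mitotic genes CDKB2 (-0.92), CycB2 (-0.78) and CDKB1 (-0.63).

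In the other lists, 1 of 7 heat shock genes rose, Hsp90-1 (0.59), and 2 rose and 1 fell when adjusted over the list alone. Of 42 ethylene and abscisic acid genes 2 rose, ACO4 (1.00, SE 0.122), which makes ethylene, and EIN2 (0.45), against 1 when adjusted over the list alone. GS2, the plastid glutamine synthetase, fell by 0.99 as 1 of 4 nitrogen genes, CHS1, a chalcone synthase, fell by 0.66 as 1 of 8 phenylpropanoid genes, and AGPL3 (-0.78) and SPS (-0.56) fell among 18 sugar and starch genes. Adjusted over the list alone, the nitrogen and phenylpropanoid counts stayed at 1, and 3 sugar and starch genes fell and 1 rose. None of 10 cytosolic translation genes passed in limma, 2 of them at an unadjusted p under 0.05, and sig1 of plastid gene expression (0.01), VPE5 of proteolysis (0.25), and mdh (-0.33) and UCP (-0.12) of respiration did not pass either, VPE5 and mdh being under 0.05 unadjusted. Markers of other tissues did not pass: 0 of 5 for meristem and 0 of 5 for root (1 in each at an unadjusted p under 0.05), 0 of 2 for epidermis and 0 of 1 for xylem (0 unadjusted). Medians and means differed in sign for the antioxidant list (0.09 and -0.08) and the nitrogen list (0.18 and -0.09), and for the root list both were within 0.02 of 0. Camera called 2 of the 13 lists tested; the smallest adjusted p among the other 11 was 0.193 (cell cycle).

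Further genes with large changes were LOC543930 (-2.09), LOC544217 (-1.50), LOC543561 (-1.28) and the aquaporin gene Aqp2 (-1.09) on the lower side. On the upper side stood LOC543942 (1.02), RDRP (0.94), DEM2 (0.93), the S-adenosylmethionine synthetase gene SAM1 (0.91), ME2 (0.90), the NADPH oxidase gene Wfi1 (0.90) and the receptor gene Eix1 (0.89). Across the array, limma called 1083 of 10101 probe sets (10.7%), 471 higher and 612 lower; of these, 196 changed at least 2-fold, 40 upward and 156 downward. The 3' over 5' difference of the actin, gapdh, ef1a and ubiquitin control probe sets, a sign of RNA quality, was higher in the psaA mutant than in wild type by 0.27, 0.28, 0.31 and 0.30, beside each group above, while those of GlutTrans and PhyB2 were -0.12 and -0.13. Of several 5' probe sets of ef1a only 1 was used. The ef1a 3' probe set gave 0.19, the 5' one used -0.12 and the other 5' ones 0.23 and 0.07. The levels of these control genes, as medians of their probe sets, differed from wild type by 0.41 (actin), 0.74 (ubiquitin), 0.18 (gapdh), 0.11 (ef1a), 0.11 (GlutTrans) and -0.06 (PhyB2), of which gapdh, ef1a and GlutTrans turned to -0.06, -0.14 and -0.14 with poly-A scaling. Of the 1083, 43.5% were higher, against 7.95% of calls with poly-A scaling, under which the rises of Hsp90-1, CHI14, AOC, APX2, AOX1a and EIN2 no longer passed. With 1 array left out the count was 498 (without psaA replicate 1), 494 (psaA replicate 2), 563 (wild-type replicate 1) and 550 (wild-type replicate 2), and leaving out at least 1 array ended the calls of Wfi1, HMGR, CHI9, CHI14, loxD, PDS, DXR, CCD1A, CAB6A, DHAR2, APX2, AOX1a, Hsp90-1, EIN2, CHS1, SPS, AGPL3, CDKB1, CDKB2 and CycB2, with adjusted p up to 0.252 (AGPL3 without psaA replicate 2).

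Loss of psbA was compared with wild type in the same way. Of 6 photosystem II genes 5 again fell, and so did 5 of 14 carotenoid and isoprenoid genes. Among named genes the largest falls were in ca2 and in a signalling gene. The gene ca2 was 4.06-fold lower (-2.02, SE 0.113, n = 2 per group) and MPK3 (543880), a mitogen-activated protein kinase gene, 3.29-fold lower (-1.72, SE 0.111). The lipoxygenase gene loxC was 2.76-fold lower (-1.46, SE 0.132), and DGK1, a diacylglycerol kinase gene, 2.39-fold lower (-1.26, SE 0.154). Higher were IAA3, an auxin-response repressor gene, 2.2-fold (1.14, SE 0.109), GluB, 2.2-fold (1.14, SE 0.112), and SAM1, 2.06-fold (1.05, SE 0.102). At further probe sets, MPK3 gave -0.99 (adjusted p = 0.014) and -0.27 (adjusted p = 0.199), and IAA3 gave 0.08 (adjusted p = 0.744). The further ca2 probe sets gave -2.29 (adjusted p = 4.4e-05), -0.07 (adjusted p = 0.78) and -0.82 (adjusted p = 0.0598), and the second VDE probe set gave -0.42 (adjusted p = 0.123).

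Of the 6 photosystem II genes 5 fell, with a median of -0.67 and the same count adjusted over the list alone. PsbQ fell by 0.81, PSBP by 0.72, CAB4 by 0.68, CAB5 by 0.66 and PSBO by 0.53, with SE from 0.102 to 0.128. PETE fell by 0.71, and CAB6A (-0.32, adjusted p = 0.15) and POR2 (-0.32, adjusted p = 0.145) did not pass. Camera called the list (adjusted p = 0.000501; adjusted p = 0.18 with an estimated correlation). Of the 14 carotenoid and isoprenoid genes 5 fell and 9 did not pass, on both counts: VDE (-1.12), ZDS (-0.72), HDS (-0.70), PSY2 (-0.58) and PDS (-0.41), with a list median of -0.26. Camera called this list too (adjusted p = 0.000501; adjusted p = 0.18 with an estimated correlation).

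Of the 24 pathogenesis-related and wound genes, GluB and PR-5 (0.50) rose, loxC, loxD (-0.78) and opr2 (-0.53) fell, and 19 did not pass; adjusted over the list alone, 2 rose and 6 fell. NP24-I rose by 0.60. Of 13 antioxidant genes, CAT2 (-1.04), DHAR2 (-0.83) and the glutathione peroxidase gene GPXle-1 (-0.81) fell and APX2 (0.48) rose, against 3 and 2 when adjusted over the list alone; with poly-A scaling APX2 gave -0.0096. Of 7 heat shock genes, HSC80 (0.83) and Hsp90-1 (0.80) rose and the plastid chaperonin gene CPN21 fell by 0.59, against 3 and 1 over the list alone. GS2 fell by 0.98 among 4 nitrogen genes (over the list alone, 1 rose and 1 fell), and CHS1 by 0.71 among 8 phenylpropanoid genes (2 over the list alone).

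TAS14 (0.58), ER43 (0.58) and EIN2 (0.54) rose among 42 ethylene and abscisic acid genes (1 over the list alone), eIF-5A3 (0.61) among 10 translation genes, and PCNA (0.57), a replication gene, among 13 cell cycle genes (2 rose and 1 fell over the list alone). None of 18 sugar and starch genes passed, 5 of them at an unadjusted p under 0.05. None of sig1 (0.04), VPE5 (-0.14), mdh (-0.37) and UCP (-0.07) passed, only mdh being under 0.05 unadjusted. Of 5 root markers Nramp2 (0.47) rose and NRAMP3 (-0.48) fell, on both counts, and with poly-A scaling Nramp2 gave -0.012. Of 5 meristem, 2 epidermis and 1 xylem markers 0 passed, with 1, 1 and 0 at an unadjusted p under 0.05. Medians and means differed in sign for the antioxidant (0.01 and -0.16) and the sugar and starch list (0.04 and -0.03). By camera against genes with a symbol none of the other 11 of the 13 lists was called, the smallest adjusted p being 0.113 (phenylpropanoids). Against all tested probe sets, a background chosen after seeing the data, camera called the phenylpropanoid list as lower (adjusted p = 0.0391), against adjusted p = 0.452 with an estimated correlation among genes with a symbol. Fry, which does not compare a list with other genes, called 8 lists, phenylpropanoids among them (adjusted p = 0.0331).

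Further changes were LOC543930 (-1.51), LOC544217 (-1.39), LOC543561 (-1.07) and Aqp2 (-1.06), and, upward, LOC543942 (1.08), CIP2b (0.90), the transaldolase gene TAL (0.79), abz1 (0.77) and LOC544187 (0.72). In all, 1128 of 10101 probe sets were called (11.2%), 546 higher and 582 lower; 160 changed at least 2-fold, 52 upward and 108 downward. The 3' over 5' differences of actin, gapdh and ef1a stood at -0.13, -0.08 and -0.09 against wild type, and those of ubiquitin, GlutTrans and PhyB2 at 0.32, 0.02 and -0.03. Their levels differed from wild type by 0.75 (actin), 0.38 (ubiquitin), -0.02 (gapdh), 0.17 (ef1a), 0.43 (GlutTrans) and -0.04 (PhyB2), of which ubiquitin, ef1a and GlutTrans turned to -0.10, -0.32 and -0.06 with poly-A scaling, and gapdh to 0.0055 with scaling on hybridisation controls. With poly-A scaling 6615 probe sets were called and 1.27% of them were higher, against 48.4% as deposited, and the rises of NP24-I, PR-5, HSC80, Hsp90-1, TAL, abz1, LOC544187, TAS14, ER43, EIN2, eIF-5A3, PCNA, APX2 and Nramp2 no longer passed. With 1 array left out the count was 618 (without psbA replicate 1), 668 (psbA replicate 2), 532 (wild-type replicate 1) and 509 (wild-type replicate 2), and leaving out at least 1 array ended the calls of CAB4, CAB5, PSBO, PSY2, HDS, PDS, opr2, NP24-I, PR-5, HSC80, LOC544187, CPN21, DHAR2, APX2, CHS1, EIN2, TAS14, ER43, eIF-5A3, PCNA, Nramp2 and NRAMP3, with adjusted p up to 0.241 (opr2 without wild-type replicate 2).

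The mutants were then compared with each other. The 4 largest differences among named genes were all lower in the psbA than in the psaA mutant: MPK3 5.03-fold (-2.33, SE 0.111, n = 2 per group), LOC544153 2.95-fold (-1.56, SE 0.106), loxD 2.83-fold (-1.50, SE 0.117) and Ve2, a receptor-like protein gene of Verticillium resistance, 2.57-fold (-1.36, SE 0.152). In each of these 4 genes the psaA mutant was called higher than wild type and the psbA mutant lower, but the calls against wild type were less firm than the difference. The genes were ranked by this difference, and it adds up 2 opposite changes. It is therefore firmer by construction and adds no support to the calls against wild type. The rise in the psaA mutant was not called without psaA replicate 2 for MPK3 (adjusted p = 0.0765) and loxD (adjusted p = 0.0543), nor with poly-A scaling for MPK3 (adjusted p = 0.111) and Ve2 (adjusted p = 0.168). Both Ve2 calls against wild type ended with either wild-type array or at least 1 array of the mutant left out, with adjusted p up to 0.17 in the psaA mutant (without psaA replicate 1) and 0.104 in the psbA mutant (without wild-type replicate 1), while the difference between the mutants passed in these 4 genes with each array left out. CAT2 was 2.15-fold higher in the psbA than in the psaA mutant (1.11, SE 0.102), and CrtR-b1 1.91-fold (0.93, SE 0.143). The second MPK3 probe set called in both mutants gave -1.88, and the other MPK3 probe set gave -0.35 with adjusted p = 0.169. For the psaA mutant against wild type these 2 probe sets gave 0.89 (adjusted p = 0.0231) and 0.07 (adjusted p = 0.772) in limma. With poly-A scaling the rise at the second MPK3 probe set was still called (0.64, adjusted p = 0.0172).

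Of the 24 pathogenesis-related and wound genes 4 were lower in the psbA mutant, on both counts: loxD, CHI14 (-1.25), AOC (-1.08) and CHI9 (-0.68). Camera put the list lower (adjusted p = 0.0089; adjusted p = 0.289 with an estimated correlation). Of the 14 carotenoid and isoprenoid genes, CrtR-b1, CCD1B (0.58), VDE (0.56) and ZEP (0.55) were higher in the psbA mutant and HMGR (-1.03) was lower; adjusted over the list alone, 6 were higher and 1 lower. Camera put this list higher, with a median of 0.28 that became 0.04 with poly-A scaling (adjusted p = 0.0089; adjusted p = 0.229 with an estimated correlation). None of the 6 photosystem II genes differed alone in limma (4 at an unadjusted p under 0.05), and 1 did when adjusted over the list alone, while camera put the list higher with a median of 0.26 that became 0.02 with poly-A scaling (adjusted p = 0.00902; adjusted p = 0.229 with an estimated correlation). Of 13 cell cycle genes PCNA was higher (0.83), and 2 were when adjusted over the list alone; camera put the list higher, with a median of 0.20 that became -0.04 with poly-A scaling (adjusted p = 0.00902; adjusted p = 0.229 with an estimated correlation). Without psbA replicate 1, none of these 4 list calls was left, each with adjusted p = 0.0583.

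**Figure D2:**
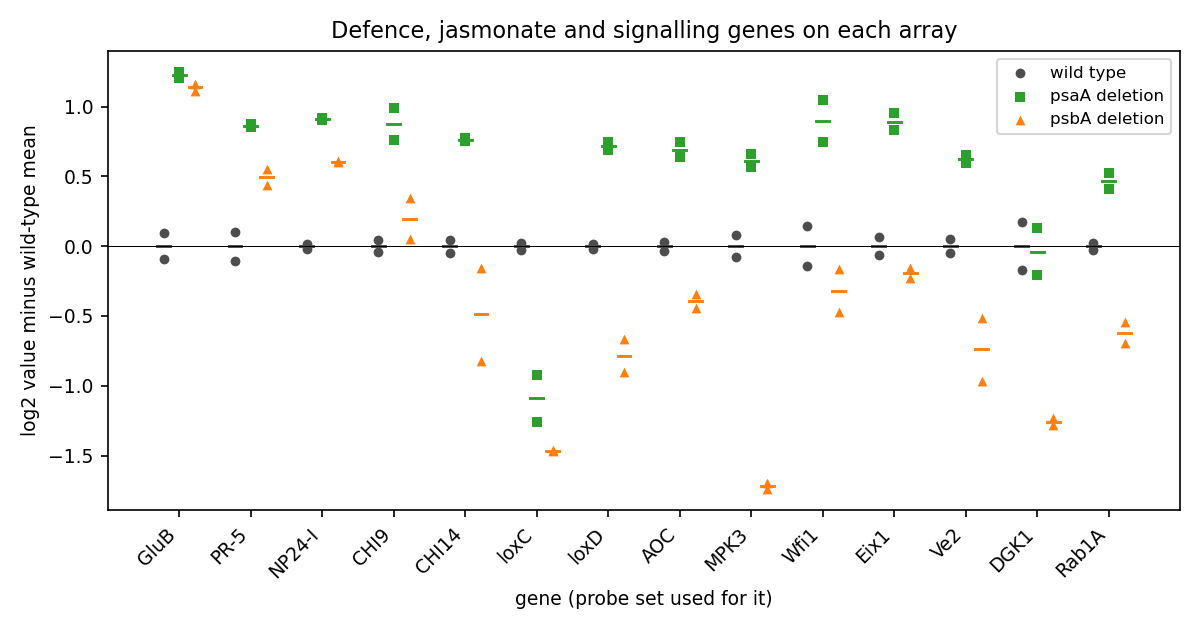
Log2 values of each array minus the wild-type mean for 14 defence, jasmonate and signalling genes, with 2 points and a line at their mean for each group. GluB was above wild type in both mutants (1.23 and 1.14), whereas MPK3 had means of 0.61 in the psaA mutant and -1.72 in the psbA mutant.

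Wfi1 (-1.22), DGK1 (-1.22), Rab1A (-1.09) and Eix1 (-1.09) were also lower in the psbA mutant, as were the antioxidant genes GPXle-1 (-0.64) and AOX1a (-0.51), the ethylene gene ACO4 (-0.58) and, of 4 nitrogen genes, gad2 (-0.47). Higher were ca2 (0.81), IAA3 (0.77), AREB1 (0.62), the blue-light receptor gene CRY1A (0.61), LOC543764 (0.60), SDH (0.58) and LOC543930 (0.57). At further probe sets ca2 gave 0.82 (adjusted p = 0.00512), 0.19 (adjusted p = 0.426) and 0.04 (adjusted p = 0.948), and CRY1A gave 0.75 (adjusted p = 0.00987). The second probe sets of IAA3 (0.03, adjusted p = 0.929), LOC543764 (0.13, adjusted p = 0.651) and VDE (0.0042, adjusted p = 0.993) did not pass. Adjusted over the list alone, 1 antioxidant gene was higher and 3 were lower, 0 ethylene genes differed and 1 nitrogen gene was lower. No gene of the heat shock, phenylpropanoid, sugar and starch, translation, meristem or root lists differed in limma (3, 2, 1, 0, 1 and 0 at an unadjusted p under 0.05), nor did CAB6A (0.38), PETE (0.11), POR2, sig1, VPE5, mdh, UCP or the epidermis and xylem markers, of which CAB6A and VPE5 were under 0.05 unadjusted. For the ethylene list the median was 0.04 and the mean -0.00081, and the smallest adjusted p among the 9 lists not called by camera was 0.385. In all, 402 of 10101 probe sets differed (3.98%), 180 higher and 222 lower in the psbA mutant, 93 of them at least 2-fold.

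From the psaA to the psbA mutant the 3' over 5' difference fell by 0.40 for actin, fell by 0.36 for gapdh and fell by 0.40 for ef1a, beside the groups above, and moved by 0.02 for ubiquitin, 0.15 for GlutTrans and 0.10 for PhyB2. For ef1a the 3' probe set gave -0.05, the 5' one used 0.34 and the other 5' ones -0.0037 and 0.42. With poly-A scaling 902 probe sets differed and 6.76% of them were higher, against 44.8% as deposited, and VDE, CCD1B, ZEP, LOC543930, AREB1, CRY1A, LOC543764 and SDH no longer passed. With 1 array left out the count was 115 (without psaA replicate 1), 133 (psaA replicate 2), 153 (psbA replicate 1), 197 (psbA replicate 2) and 266 (without either wild-type array), and leaving out at least 1 array ended the calls of Wfi1, HMGR, CHI9, CHI14, ca2, CrtR-b1, CCD1B, VDE, ZEP, PCNA, IAA3, AREB1, CRY1A, LOC543764, LOC543930, SDH, GPXle-1, AOX1a, ACO4 and gad2, with adjusted p up to 0.225 (ZEP without psaA replicate 1).

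Both mutants shared many changes. GluB, SAM1, LOC543942 and TAL were among 222 probe sets called higher in both mutants, and ca2, CAT2, VDE, loxC, Aqp2 and GS2 among 384 called lower in both. Independent lists of these lengths would share 25.5 higher and 35.3 lower probe sets. Another 27 probe sets were called in opposite directions. The shared wild-type arrays alone make opposite calls rarer, so this number was not judged against independent lists. With poly-A scaling, 42 probe sets were called higher and 1417 lower in both mutants. Across probe sets, which are not independent replicates, the changes of the mutants correlated with Pearson r = 0.678 and Spearman rho = 0.591, where the shared wild type alone gave 0.499 in simulation. The covariance was 0.0757 against a simulated 0.00918, a difference of 0.0665. The wild type, with 2 arrays, was not split between the comparisons, so how many of the shared calls come from the common wild-type arrays was not measured. Shared calls numbered 324 and 330 without psaA replicate 1 and 2, 386 and 379 without psbA replicate 1 and 2, and 303 and 290 without wild-type replicate 1 and 2.

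**Figure D3:**
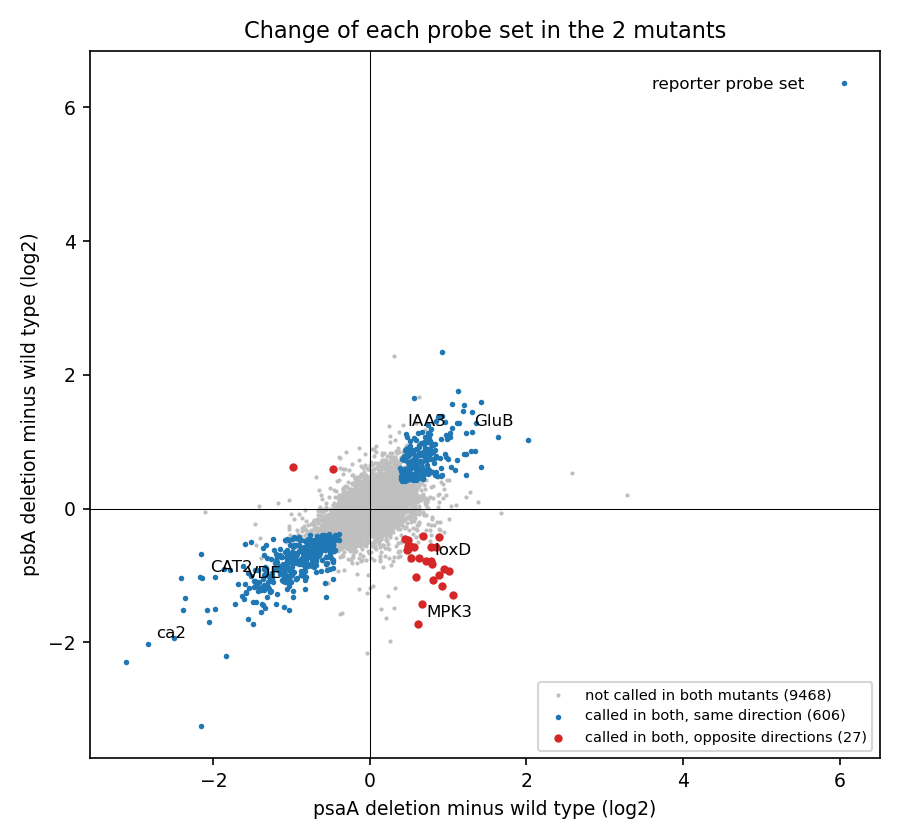
Log2 change of each of the 10101 tested probe sets in the psaA mutant (horizontal axis) and the psbA mutant (vertical axis), with probe sets called in both mutants in blue (606, same direction) or red (27, opposite directions). MPK3 and loxD lie in the lower right part of the plot, and 1 reporter probe set lies at 6.05 and 6.37.

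The largest change on the arrays was at RPTR-Les-A00196-1_s_at, 1 of 63 probe sets with the prefix for reporter sequences and without a gene name in the annotation. It was 66.5-fold higher in the psaA mutant (6.05, SE 0.115, adjusted p = 7.4e-08) and 82.5-fold higher in the psbA mutant (6.37, SE 0.115, adjusted p = 4.86e-08), with no difference called between the mutants (0.31, adjusted p = 0.201). The largest change among the other reporter probe sets was 0.513 in size.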

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

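The tests of explanations in this part, and the use of the control probe sets, were chosen after the results were seen, while the difference between the mutants was a planned test. A group of 27 probe sets was called in opposite directions in the mutants, by the test of each mutant against wild type. Since both comparisons share the wild-type arrays, which makes opposite calls rarer, their number was not judged against independent lists. Opposite calls make the difference between the mutants large by selection, so its test adds no separate support for these probe sets. The named genes among them, with psbA minus psaA on the log2 scale, were MPK3 (-2.33, and -1.88 at a second probe set), LOC544153 (-1.56), loxD (-1.50), Ve2 (-1.36), Rab1A (-1.09), FPPS1 (-1.07), a farnesyl diphosphate synthase gene, and ADC (-0.96), an arginine decarboxylase gene. Each of them was higher than wild type in the psaA mutant and lower in the psbA mutant, as were 25 of the 27 probe sets. Scaling on the poly-A controls ended the call of a rise in the psaA mutant at 13 of the 25, among them 1 probe set of MPK3 and those of Ve2, Rab1A, FPPS1 and ADC. With 1 array left out in turn, 6 of the 25 kept both calls against wild type while 25 kept both directions and 23 kept the difference between the mutants, ADC losing it without psaA replicate 1 (adjusted p = 0.0549). Rab1A kept its directions (0.41 to 0.53 in the psaA mutant, adjusted p up to 0.168 without psaA replicate 1, and -0.69 to -0.55 in the psbA mutant, adjusted p up to 0.0664 without wild-type replicate 2).

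A single array as the source is argued against only for the probe sets called in opposite directions without that array, taken as a set. This set is not limited to the group called on all 6 arrays. In the set, the unused array lay in the direction called. Its median distance was at least 0.70 on the log2 scale for each of the 6 arrays. For a wild-type array, distance was taken from the nearer mutant. The smallest distance, 0.156 at psbA replicate 2, was below the replicate standard deviation of 0.229. It belonged to CHI14, which limma did not call in the psbA mutant on all arrays (adjusted p = 0.159). The probe sets whose calls ended without an array are left out by this choice, so for them a single array stays open. RNA quality stays open, since the 3' over 5' difference shifted by up to -0.40 from the psaA to the psbA mutant in actin, gapdh and ef1a, though not in 3 other control genes. For ef1a the shift depends on which 5' probe set is used. The probe positions of the genes called in opposite directions are not used here. Handling or wounding of the leaves of one genotype could also raise or lower jasmonate genes, and 4 genes of the wound list were lower in the psbA than in the psaA mutant, which does not separate handling from genotype. The deletion itself, photosystem I against photosystem II, is the biological difference the design names, and it stays open and untested.

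The poly-A control probe sets, outside the tested set, were higher than in wild type by a median of 0.247 in the psaA mutant and 0.486 in the psbA mutant. Brightness or scaling of whole arrays is argued against by the hybridisation controls, whose medians differed from wild type by at most 0.0459 in size. A lower share of messenger RNA in the mutants' total RNA may raise the controls, and so may unequal amounts of control RNA added. These cannot be told apart here: the 4 control genes rose by at least 0.218 each, and within a mutant their rises lay within 0.111 of each other, which both would give. Of the 222 probe sets called higher in both mutants, 42 were still called higher in both after scaling on these controls and 180 were not.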

How the results depend on the processing

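Scaling on control probe sets and the background of all tested probe sets were chosen after seeing the data, and the other alternatives before. Array medians set to 0, array weights, the trend and robust fit, 1 probe set per gene, scaling on hybridisation controls and leaving out probe sets that can measure several transcripts moved no count of calls by over 1.5 times. A 2-fold minimum left 196 (psaA against wild type), 160 (psbA against wild type), 93 (psbA against psaA) and 93 shared in one direction, and treat against 1.2-fold left 380, 367, 132 and 205, as stricter thresholds must. With only the 4 arrays compared, 266 probe sets differed between the mutants, a fit with fewer degrees of freedom. Scaling on poly-A controls gave 1623 (psaA against wild type), 6615 (psbA against wild type), 902 (psbA against psaA) and 1459 shared in one direction, because it shifts all probe sets of an array. This scaling kept 741 of the 1083 main calls for psaA against wild type. For psbA against wild type it kept 666 of 1128, and for psbA against psaA 283 of 402. It turned APX2 to -0.0096, Nramp2 to -0.012, TPRP-F1 to -0.0305 and Cel3 to -0.0866 in the psbA mutant. Leaving out 1 array, where the lone array is assumed to vary like the other groups, gave 494 to 994 calls for psaA, 509 to 842 for psbA, 115 to 266 between the mutants, 290 to 386 shared in one direction, a correlation of 0.637 to 0.707, and 0 to 4 lists called between the mutants.

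Camera with an estimated correlation called 0 lists in each comparison, with 11 list calls lost counting the pooled photosynthesis list. The estimates were -0.0805 (photosystem II), 0.00828 (carotenoids and isoprenoids), -0.0152 (cell cycle) and -0.00878 (pooled list), below the preset of 0.01. This argues against a higher correlation as the cause of the losses in these lists. The pathogenesis-related list had 0.0521. With an estimated correlation camera also uses the 3 residual degrees of freedom of the fit, which it does not with a preset. This raises its p-values whatever the correlation. How much of the losses it accounts for was not tested, nor were other causes. Fry, which does not compare a list with other genes, called 8 lists for psbA against wild type and 3 in each other comparison. With all tested probe sets as background camera called 2, 3 and 4 lists. Of 167 called values of named genes, poly-A scaling ended 36 and turned 4, the fit of 4 arrays ended 26, the trend and robust fit 15, hybridisation controls 9, array weights 7, array medians 3, and leaving out 1 array 40 to 65; with an array left out none turned sign. The replicate numbers did not pair the arrays (correlations of same-numbered deviations -0.00489, -0.00856 and 0.021). With the replicate block 916, 965, 301 and 502 probe sets were called, each within 1.5 times, and 23 named values were no longer called. A second quantile normalization and both filters on dim probe sets were not run, because the centred values hold no level. Signal over background is unknown for the same reason, so a change at a probe set near background may be misstated in either direction.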

Other observations

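The lists in the next paragraphs, and the tests in this part, were chosen after the data had been seen. Of 10 S-adenosylmethionine and polyamine genes, 3 rose and 2 fell in the psaA mutant and 2 rose and 3 fell in the psbA mutant. SAM1 rose by 0.91 and 1.05, and SAHH, the adenosylhomocysteine hydrolase gene, rose by 0.76 and 0.58 (the latter gave 0.09 after scaling on poly-A controls). SPE4 fell by 0.85 and 0.72. MET1 fell by 0.70 in the psaA mutant, but its symbol alone placed it in this list, and the gene may have another function. The gene adc1 fell by 0.60 in the psbA mutant (other probe sets gave -0.48, -0.59 and 0.22, the last pair with adjusted p of 0.134 and 0.58). ADC rose by 0.49 in the psaA mutant and fell by 0.47 in the psbA mutant. Among 15 genes for 14-3-3 proteins and MAP kinases, MPK3 and MEK1 (0.63) rose and MKK3 fell by 0.80 in the psaA mutant, and MKK4 rose by 0.70 and MPK3 fell by 1.72 in the psbA mutant. Against genes with a symbol, camera called neither list in any comparison, the smallest adjusted p being 0.0608 for the kinases in the psaA mutant. Against all tested probe sets it called the kinase list, as higher in the psaA mutant than in wild type (adjusted p = 0.0304) and as lower in the psbA than in the psaA mutant (adjusted p = 0.0323). These gave adjusted p = 0.268 and adjusted p = 0.304 with an estimated correlation against genes with a symbol. Leaving out at least 1 array ended the calls of SPE4, MET1, ADC, adc1, MKK3, MEK1 and MKK4, of SAHH in the psbA mutant and of MPK3 in the psaA mutant, with adjusted p up to 0.183 (ADC in the psbA mutant without wild-type replicate 2). MEK1, MKK4, and the rises of ADC and of MPK3 at the probe set used were not called after scaling on poly-A controls. A second MPK3 probe set was still called higher in the psaA mutant by limma (0.64, adjusted p = 0.0172).

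Of 51 cell wall genes 5 fell in each mutant, with 1 higher in the psaA mutant (PMEU1, 0.58) and 2 in the psbA mutant (TPRP-F1, 0.46, and Cel3, 0.40, which turned to -0.0305 and -0.0866 after scaling on poly-A controls). The beta-galactosidase genes TBG7 (-0.77 and -0.50) and TBG6 (-0.45 and -0.62) and the expansin gene exp9 (-0.65 and -0.44) fell in both. Of 14 photoreceptor and light signalling genes, CIP2b rose in both mutants (0.76 and 0.90) and CRY1A in the psbA mutant (0.59). Of 16 auxin and gibberellin genes 0 passed in limma in the psaA mutant (3 at an unadjusted p under 0.05) and 1, IAA3, in the psbA mutant. These 3 lists were not called by camera, with adjusted p from 0.19 upward. Calls of TBG7, TBG6, TPRP-F1, Cel3 and PMEU1, and of exp9 and CRY1A in the psbA mutant, ended with at least 1 array left out, with adjusted p up to 0.244 (TBG7 in the psbA mutant without wild-type replicate 1), and those of PMEU1 and CRY1A also after scaling on poly-A controls. The photosystem, electron transport and tetrapyrrole lists pooled held 9 genes, of which 7 fell in the psaA mutant and 6 in the psbA mutant.

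The probe set RPTR-Les-A00196-1_s_at stood 5.90 above the highest wild-type array, on the log2 scale, on the lowest mutant array. Scaling argues little for this: after scaling on the poly-A controls the smaller of the changes in the mutants was 5.81. A shift of all reporter probe sets is argued against by the others of the 63, whose largest change was 0.513 in size. As a hypothesis, the probe set may report a marker gene that the mutants carry and wild type lacks, since the growth text names spectinomycin selection, though for all 6 samples alike. The sequence behind the probe set is not given in the sources used here, so this stays open.

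Some of the largest changes were at probe sets without a gene name. One of them was 3.28 higher in the psaA mutant than in wild type on the log2 scale and gave -3.08 for psbA minus psaA, and another gave -3.24 in the psbA mutant against wild type.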
